A study of Mus musculus with 30 samples.

How the data were processed

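The series holds 30 mouse samples: 6 array samples of RNA, 23 chromatin immunoprecipitation sequencing (ChIP-seq) libraries and 1 mock immunoprecipitation. RNA came from E2A-/- pre-pro-B cells, EBF-/- pre-pro-B cells and RAG1-/- pro-B cells, with 2 samples each. Per the labels' protocols, both pre-pro-B cultures grew on S17 stromal cells with IL-7, SCF and FLT3 ligand, whereas RAG1-/- cells were enriched from bone marrow by B220 and expanded for 10 d with IL-7 and SCF. Genotype and culture therefore cannot be told apart in any comparison with RAG1-/- cells. ChIP-seq covered E2A, EBF1, FOXO1, CTCF and 5 histone marks in RAG1-/- cells, and E2A with the same 5 marks in EBF-/- cells. E2A and H3K4me1 were also profiled in E2A-/- cells and in A12 cells, a T cell line that lacks E2A, both carrying a tamoxifen-activated E2A protein. That protein, E47-ER, is full-length E2A fused to the hormone-binding part of the estrogen receptor, and the bHLH-ER form used as its counterpart lacks the transactivation domains. Per the labels' protocols, tamoxifen (1 µM) was given for 1 or 6 h after 21 h of culture, and infected cells were enriched by a surface tag.

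The arrays were scanned with Agilent Feature Extraction 9.5.3.1, per the file headers, and the deposited intensity values were background-subtracted, detrended and dye-normalized within each array by linear and LOWESS factors. The 6 samples sat on 4 two-colour arrays of 1 slide in 1 scan, so neither slide nor scan could act as a batch. Array 1 carried E2A-/- replicate 1 in Cy5 and RAG1-/- replicate 1 in Cy3, and array 2 carried EBF-/- replicate 1 in Cy5 and E2A-/- replicate 2 in Cy3. EBF-/- replicate 2 was the Cy3 channel of array 3 and RAG1-/- replicate 2 the Cy5 channel of array 4. The labels describe no RNA for the other channel of arrays 3 and 4, which was not used here. Each group thus held 1 sample in each dye. Samples that shared an array had identical copies of its file, and each sample was read from the channel of its own dye.

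Processed signals were put on a log2 scale, quantile normalized over the 6 assigned channels and averaged over the spots of a probe, with control spots and outlier spots left out. Of 41099 probes with a value in all 6 channels, 22132 were well above background in both samples of at least 1 group and were kept. The brightest kept probe stood for its gene, which left 12590 genes. Other kept probes existed for 5171 genes, and of these 10, 55 and 20 had probes called in opposite directions in EBF-/- against E2A-/-, RAG1-/- against EBF-/- and RAG1-/- against E2A-/-. Gene names were updated through a table of RefSeq genes of assembly GRCm38.p6, used for names only: of 41174 probes, 23483 matched by accession, 6678 by current symbol and 2887 by a unique synonym, 1321 kept the name in the file, and 6805 had none. Genome positions of probes are those of the array design, build mm8, per the file headers.

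All 6 samples entered 1 fit in limma 3.58.1 (R 4.3.3) with group and dye as terms, array as a random block and a trended prior, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The array correlation (-0.036) was estimated without the dye term, since limma could not estimate it with 2 residual degrees of freedom, and was reused in the alternatives. The prior added 2.50 degrees of freedom. Nothing in the labels says that replicates came from separate animals or cultures. The RAG1-/- samples differed in Xist and Y-linked transcripts and so were not the same cells, while in the other groups the spread that p-values measure may be technical. Errors of log2 changes are standard errors of the fit (SE, n = 2 per group). They and the p-values draw on the spread within all 3 groups, also where 2 groups are compared. A gene with no probe well above background in either sample of a group has only a bound there. Where another of its probes was well above background, the fitted change is kept even if the probe used was dim in both samples. Where 1 of the 2 samples was well above background the fitted change is given, and its size rests partly on a dim sample. A change with a bound only is given as "at least N-fold", the bright group's mean against the dim group's mean of, per sample, the higher of the probe's own value and the lowest signal among probes well above background. In data simulated for EBF-/- against E2A-/- over 12590 genes, the fit called 44 of 67 genes changed by 1 on the log2 scale, 56 of 67 changed by 2 and 63 of 66 changed by 4, with 15 false calls among 178. The simulated noise was normal and independent between samples, with the fit's own spread per gene. Far fewer genes were changed than the 3020 called in the data. These rates therefore need not carry over to the real comparison.

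The groups, comparisons, tests, 18 gene lists, most alternatives and the rule for named genes were chosen before the data were examined. Named genes are the 12 with the largest change in each direction among called genes whose samples do not overlap between groups, up to 4 members of each list by adjusted p, and Tcf3 (the gene of E2A), Ebf1, Rag1, Foxo1, Pax5 and Ctcf. The text gives a part of them. The lists covered the pre-B receptor and its signalling, B-lineage transcription factors, B cell surface, V(D)J recombination, multipotent progenitors, T, NK, myeloid, mast, erythroid, dendritic and stromal cells, the cell cycle, E and Id proteins with Notch targets, FOXO and IL-7 receptor targets, interferon response, ribosomal proteins and stress genes. Some genes stand in more than 1 list, such as Rag1, Id2, Gfi1b and Il7r. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 54 tests (18 lists in 3 comparisons). Camera with an estimated correlation and fry, limma's test of whether a list's genes move on balance one way, were run beside it. The estimated correlation and the test that uses it rest on 2 residual degrees of freedom. Hardly any list could pass that test after adjustment over 54 tests, so a failure there decides nothing about a list. The preset of 0.01 is in turn an assumption.

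Peak lists were deposited as intervals with a whole-number score for each peak. Per the submitters' processing notes the tool was HOMER and the build mm8; the aligner, thresholds, control library and meaning of the authors' score are not given in the sources used here. Each list stood for 1 library. Intervals had 1 width per list, 200 bp for factors except FOXO1 (76 bp), 1000 bp for histone marks and 60 bp for the mock list. Lists were compared by overlap of at least 1 bp, in Python 3.11.15 with numpy 2.4.6, and 5 overlaps were checked against bedtools 2.31.1 with equal counts. Percentages carry Wilson 95% intervals, which cover counting error only, and no test was made between conditions with 1 library each. The percentage from chance positions is the mean of 100 circular shifts of the second list within chromosomes. Scores were used only to rank peaks within a list. The number of reads behind each list is unknown, so a longer list may come from a deeper library. Array genes were set against peaks within 50 kb of the probe, which lies near the 3' end of the transcript and not at its start, for 12562 genes with coordinates. Fisher's exact test (two-sided, scipy 1.17.1) compared called with not called genes, adjusted over 30 tests for factor lists and over 20 for histone lists. Motifs under peaks were not analysed here, because no mm8 sequence was used.

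Alternatives to the array fit were normexp background correction (offset 50), 75th percentile scaling, no filter on dim probes or only probes well above background in all 6 channels, no dye term, no array block, a replicate block, no trend, only the 4 samples compared, the mean of a gene's probes, and each sample left out in turn. For peaks they were overlap of 50% of the shorter peak, the upper 50% of each list by score, lists of equal length, removal of peaks in the mock list, distances of 20 and 100 kb, and matching by expression tertile. A crossed replicate block, a fit without E2A-/- replicate 1, RAG1-/- replicate 2 and the dye term, and the list tests with each sample left out were added after the data were seen. So were the tests of genes near EBF-/- E2A peaks and near histone peaks, and the counts of genes near several factors.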

Results

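Gene expression was measured in cells arrested at successive steps of early B cell development by loss of E2A, EBF1 or RAG1, and the binding of E2A, EBF1, FOXO1 and CTCF was mapped beside histone marks in the same kinds of cells. E2A and EBF1 are transcription factors needed to enter the B lineage, FOXO1 acts with them at the pro-B stage, CTCF organises chromatin loops, and RAG1 cuts antigen receptor genes, so that RAG1-/- pro-B cells are committed but cannot complete a receptor. The 3 array groups held 2 samples each. Of 43379 probe spots, 61.8% were well above background in E2A-/- replicate 1 and 40.9% in replicate 2, 44.2% and 51.6% in the EBF-/- samples, and 54.8% and 54.7% in the RAG1-/- samples. Across genes, replicates correlated with Pearson's r of 0.977 (E2A-/-), 0.988 (EBF-/-) and 0.981 (RAG1-/-), with genes not independent of one another. Between replicates, 1016 of 12590 genes were more than 2-fold apart in E2A-/-, 574 in EBF-/- and 623 in RAG1-/-.

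The targeted genes were read in every sample first. Tcf3, which encodes E2A, had normalized log2 intensities of 10.80 and 9.45 in the E2A-/- samples, 13.42 and 13.40 in EBF-/-, and 15.04 and 14.73 in RAG1-/-. Ebf1 stood at 10.87 and 10.91 in the EBF-/- samples, above 6.94 and 5.38 in E2A-/- and below 12.55 and 12.38 in RAG1-/-. A second, dimmer Ebf1 probe read 4.54 and 3.42 in EBF-/-, under the lowest well-measured signals of those samples (6.26 and 5.21), 8.36 and 8.26 in RAG1-/-, and 3.01 and 3.03 in E2A-/-. A second Tcf3 probe read 10.46 and 10.35 in E2A-/-, 10.80 and 11.13 in EBF-/-, and 12.66 and 12.64 in RAG1-/-. Rag1 stood at 10.52 and 11.12 in the RAG1-/- samples, higher than in both other groups. Where these probes lie relative to the deleted parts of the genes is not given in the sources used here, so these signals check no label, and the 2 Ebf1 probes differ on whether EBF-/- cells hold the transcript. Foxo1 read 8.61 and 7.02 in E2A-/-, 8.41 and 8.40 in EBF-/-, and 13.94 and 13.97 in RAG1-/-. Pax5, the factor that fixes B cell commitment, read 9.37 and 6.84 in E2A-/-, 7.04 and 6.55 in EBF-/-, and 14.22 and 14.00 in RAG1-/-, with E2A-/- replicate 2 not well above background.

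**Figure D1:**
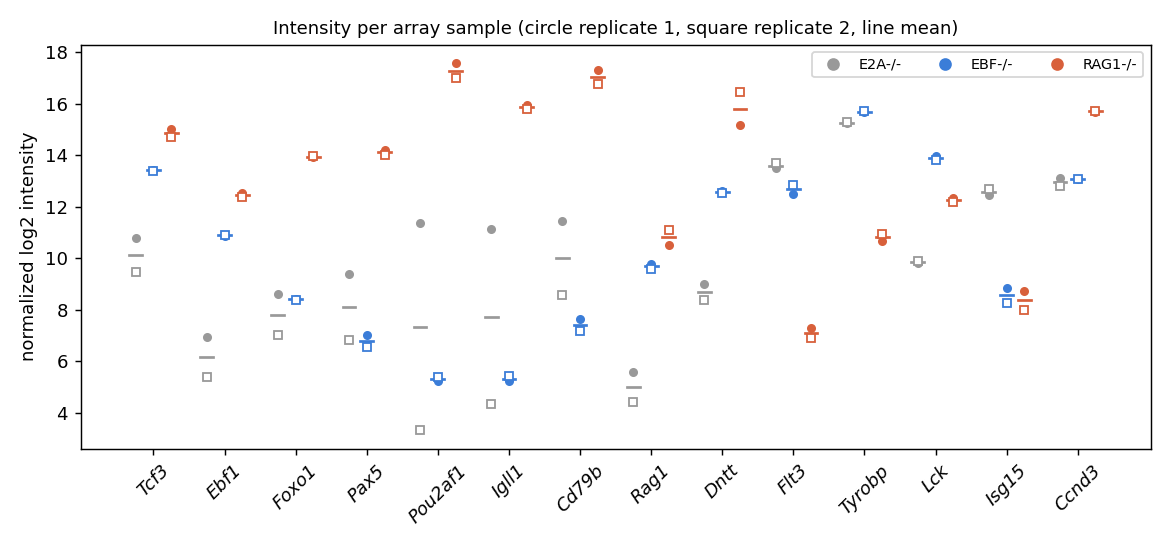
Normalized log2 intensity (y axis) of 14 genes in each array sample, by group (E2A-/-, EBF-/- and RAG1-/-), with a circle for replicate 1, a square for replicate 2 and a line for the mean of 2. Foxo1 lies at 8.41 and 8.40 in the EBF-/- samples and at 13.94 and 13.97 in the RAG1-/- samples, and Igll1 differs between the E2A-/- replicates (11.13 and 4.33).

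EBF-/- against E2A-/- asked what differs between cells that have E2A but lack EBF1 and cells that lack E2A. As lists, T-lineage genes (7 of 11 higher) and NK genes (5 of 11) shifted up in EBF-/- cells, and interferon-response (10 of 12 lower) and myeloid genes (4 of 13) shifted down, by camera with its preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.647 with an estimated correlation for each, 0 of 54 list tests passing and 1 at an unadjusted p under 0.05, where fry passed 21). With 2 residual degrees of freedom that test could hardly pass any list, so its failures here and below decide nothing. Lck, a kinase of T cell receptor signalling, rose by 4.03 on the log2 scale (SE 0.11, 16.3-fold, limma adjusted p = 0.00192), and Thy1, a T cell surface protein, by 4.71 (SE 0.52). Isg15, a ubiquitin-like protein induced by interferon, fell by 4.03 (SE 0.33, adjusted p = 0.0042). Csf1r, the receptor that macrophages need for growth, fell by 5.71 (SE 0.83, 52.2-fold, adjusted p = 0.0141). In all, 1601 genes were higher and 1419 lower in EBF-/- cells, 794 and 686 of them by more than 2-fold, and 148 of the higher and 120 of the lower have a bound only.

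The genes with the largest rise in EBF-/- cells included Stag3, a cohesin subunit of meiosis, at least 125-fold higher (adjusted p = 0.00207), and the C region of the T cell receptor gamma chain, Tcrg-C, at least 28.5-fold higher (adjusted p = 0.00257). Ppic, a cyclophilin, rose by 8.07 (SE 0.38), and Ptprf, a receptor tyrosine phosphatase, by 7.32 (SE 0.66). Ptger3, a prostaglandin E receptor, was at least 22.3-fold higher. Among the largest falls, Mmp8, the collagenase of neutrophils, was at least 39.7-fold lower and Clec5a, a receptor of myeloid cells, at least 23.3-fold lower. Trem2 and Gpnmb, both known from macrophages, were at least 21.2-fold and at least 23.9-fold lower. Oas1f, of the interferon-induced oligoadenylate synthetase family, fell by 5.71 (SE 0.49). At its brightest probe Ebf1 itself rose by 4.72 (SE 0.48, adjusted p = 0.0062), Rag1 by 4.70 (SE 0.27, adjusted p = 0.00271) and Tcf3 by 3.27 (SE 0.43, adjusted p = 0.0111). The second Ebf1 probe was dim in both groups, and the second Tcf3 probe differed far less (10.80 and 11.13 against 10.46 and 10.35). Foxo1 (0.58, SE 0.45, adjusted p = 0.413), Pax5 (-1.33, SE 0.70, adjusted p = 0.241) and Ctcf (0.26, SE 0.09, adjusted p = 0.113) did not pass.

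Of 11 measured T-lineage genes, 7 rose and 1 fell, with a median of 1.99 (camera adjusted p = 0.00646). Zap70, the kinase next to Lck in the receptor pathway, rose by 2.95 (SE 0.24). Of 11 NK and cytotoxic genes, 5 rose and 1 fell, and 6 rose when adjusted over the list alone (median 1.83, camera adjusted p = 0.00646). They included Id2, an inhibitor of E proteins, which rose by 1.45 (SE 0.12), Tbx21, a factor of NK and Th1 cells (2.91, SE 0.48), and Gzma, a granzyme (at least 9.03-fold). Interferon-response genes fell for 10 of 12 members and for 12 of 12 when adjusted over the list alone (median -4.00, camera adjusted p = 3.8e-06), among them Ifih1, a sensor of viral RNA (-2.26, SE 0.13). The EBF-/- samples differed on this list, 3 of 12 genes being more than 2-fold dimmer in replicate 2 (median of replicate 2 less replicate 1, -0.53), such as Oas1a (10.41 and 6.98) and Ifit3 (8.96 and 5.18). Of 13 myeloid genes, 4 fell and 1 rose (median -1.17, camera adjusted p = 0.0355), or 5 and 1 when adjusted over the list alone, and the list missed the threshold without E2A-/- replicate 2 (adjusted p = 0.114). Cd68, a lysosomal protein of macrophages, fell by 3.49 (SE 0.27) and Fcgr3, an IgG receptor, by 0.89 (SE 0.10), whereas Csf2ra, a chain of the GM-CSF receptor, rose by 0.77 (SE 0.08). The adjusted p of these 4 lists was 0.647 with an estimated correlation. By fry the myeloid list did not pass (adjusted p = 0.109), and the other lists did.

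Pre-B receptor genes had a median of -1.41 and passed camera (adjusted p = 0.0355), with 1 of 14 members higher and 1 lower, and adjusted p = 0.722 with an estimated correlation. They did not pass by fry (adjusted p = 0.296). Syk, a kinase of the receptor, rose by 1.32 (SE 0.13), and Bank1, a scaffold of B cell signalling, fell by 2.33 (SE 0.30). In E2A-/- replicate 1, 9 of the 14 genes were more than 2-fold brighter than in replicate 2, with a median of replicate 2 less replicate 1 of -2.68. Without E2A-/- replicate 1 the list's median was -0.03, so its shift rests on that sample. The EBF-/- samples lay close together on the list, with a median of replicate 2 less replicate 1 of 0.09. B-lineage transcription factors passed as higher without E2A-/- replicate 1 (adjusted p = 0.012) and as lower without E2A-/- replicate 2 (adjusted p = 0.0435), and B cell surface genes as lower without E2A-/- replicate 2 (adjusted p = 0.0332). With all samples, 3 of the 16 B-lineage factors were higher (camera adjusted p = 0.971), Ebf1, Myb and Runx1, and the list's median (-0.17) and mean (0.20) differed in sign.

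Among 11 genes of V(D)J recombination, 5 rose and 2 fell (median 0.39, camera adjusted p = 0.0786, and 0.02 without EBF-/- replicate 2). Dntt, the polymerase that adds bases at receptor junctions, rose by 3.87 (SE 0.30), and Xrcc5, which encodes Ku80 of end joining, by 4.93 (SE 0.16), with 1 of the E2A-/- samples well above background. In progenitor genes, Hoxa9 (1.44, SE 0.12) and Il7r, the receptor for IL-7 (1.59, SE 0.16), rose, and Flt3, a cytokine receptor of early progenitors (-0.91, SE 0.10), and Ly6a (-3.03, SE 0.42) fell, with no shift of the list (adjusted p = 0.868). B cell surface (adjusted p = 0.868), dendritic cell (0.911), cell cycle (0.477), FOXO and IL-7 receptor target (0.229), stress (0.181), erythroid (0.833), mast cell (0.847), stromal (0.868) and ribosomal protein (0.277) lists did not pass. Median and mean differed in sign for the stromal and mast cell lists. The list of E and Id proteins with Notch targets (adjusted p = 0.847) had a median of -0.17 and a mean of 0.52. In it Gfi1b, a zinc-finger repressor, rose by 3.95 (SE 0.17), and Tcf4, another E protein, fell by 1.35 (SE 0.11). Bcl6 fell by 2.50 (SE 0.13), and Ccnd2, cyclin D2, by 1.40 (SE 0.09).

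The number of calls in this comparison moved with every sample left out. It was 701 higher and 470 lower without E2A-/- replicate 1, 666 and 502 without E2A-/- replicate 2, 279 and 311 without EBF-/- replicate 1, 207 and 217 without EBF-/- replicate 2, 2744 and 2488 without RAG1-/- replicate 1, and 2741 and 2491 without RAG1-/- replicate 2. A fit without E2A-/- replicate 1, RAG1-/- replicate 2 and the dye term called 1614 and 1247 genes.

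RAG1-/- against EBF-/- set committed pro-B cells against cells stopped before EBF1 acts. Igll1 (lambda 5), a part of the surrogate light chain, rose by 10.63 (SE 1.92, limma adjusted p = 0.0135), Vpreb1, its other part, by 9.48 (SE 0.86), and Cd79b, a signalling chain, by 9.67 (SE 0.84). Igll1 lay close within RAG1-/- (15.95 and 15.79) and EBF-/- (5.24 and 5.41). Its SE carries the spread of the E2A-/- samples (11.13 and 4.33), which share the fit. Tyrobp, an adaptor of NK and myeloid receptors (-4.89, SE 0.11, adjusted p = 0.000371), and the progenitor gene Flt3 (-5.58, SE 0.10, adjusted p = 0.000371) fell. By camera with its preset correlation NK (11 of 11 lower), T-lineage (6 of 11) and progenitor genes (9 of 12) shifted down and cell-cycle genes (19 of 24 higher) up, with adjusted p = 0.647 with an estimated correlation for each. A total of 2594 genes were higher and 2939 lower in RAG1-/- cells, 1300 and 1564 of them by more than 2-fold, and 368 of the higher and 206 of the lower have a bound only.

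Vpreb3 rose by 12.21 (SE 2.95, adjusted p = 0.0304), Pou2af1, a coactivator of B cell octamer promoters, by 12.06 (SE 2.32, adjusted p = 0.0162), and Lef1, a Wnt-pathway factor of pro-B cells, by 9.71 (SE 1.52). Each was well above background in 1 of the EBF-/- samples. For Pou2af1 (5.24 and 5.41) and Lef1 (5.40 and 5.37) the EBF-/- samples lay close together. The E2A-/- samples, which share the fit, lay apart (11.35 and 3.31, 8.77 and 3.16), and the SE carries that spread. Grb7, an adaptor protein, was at least 327-fold higher, and Enpep, the aminopeptidase known as the pro-B and pre-B marker BP-1, at least 167-fold higher. Alpl, an alkaline phosphatase, was at least 230-fold higher. Among the largest falls, Il18r1, a cytokine receptor of T and NK cells, was at least 378-fold lower (adjusted p = 0.000355), and Hoxa10, a homeobox factor of progenitors, at least 153-fold lower. Ccr9, a chemokine receptor of thymus-homing cells, fell by 9.11 (SE 0.45) and Txk, a T cell kinase, was at least 72.6-fold lower. Pdcd1, which encodes PD-1, fell by 7.43 (SE 0.90) and Jchain, the joining chain of antibodies, by 7.50 (SE 1.01). Foxo1 rose by 5.57 (SE 0.44, adjusted p = 0.00171), Pax5 by 7.35 (SE 0.69, adjusted p = 0.00249), Tcf3 by 1.49 (SE 0.42, adjusted p = 0.0475), Rag1 by 1.14 (SE 0.27, adjusted p = 0.0293) and Ctcf by 0.75 (SE 0.09, adjusted p = 0.00455). At its brightest probe Ebf1 missed the threshold (1.60, SE 0.47, adjusted p = 0.0515), whereas its second probe read 8.36 and 8.26 in RAG1-/- against 4.54 and 3.42 in EBF-/- cells.

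Of 14 pre-B receptor genes, 11 rose and 1 fell, and 12 rose when adjusted over the list alone (median 7.51, camera adjusted p = 0.000797). Blnk, the adaptor that carries the receptor's signal, rose by 6.93 (SE 0.37) and Cd79a was at least 24.1-fold higher. Of 16 B-lineage factors, 10 rose and 1 fell (camera adjusted p = 0.0217), with Ikzf3 up by 2.82 (SE 0.23) and Bcl11a by 1.40 (SE 0.12). Of 12 B cell surface genes, 7 rose and 1 fell (camera adjusted p = 0.0199). Ms4a1 (CD20) was at least 63.1-fold and Cd38 at least 17.4-fold higher, while Ptprc (CD45) fell by 1.22 (SE 0.13). With an estimated correlation the adjusted p was 0.647 for the pre-B list, 0.722 for the factors and 0.667 for the surface genes. By fry these lists did not pass either (adjusted p = 0.0571, 0.0855 and 0.0815). In V(D)J recombination 4 of 11 genes rose (camera adjusted p = 0.062), including Dntt (3.25, SE 0.30) and the ligase gene Lig4 (4.16, SE 0.15).

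All 11 NK and cytotoxic genes fell (median -4.75, camera adjusted p = 2.21e-05), with Klrd1, an NK receptor chain, down by 4.95 (SE 0.18) and Id2 down by 2.67 (SE 0.12). Among 11 T-lineage genes, 6 fell and 1 rose, and 8 fell when adjusted over the list alone (camera adjusted p = 0.0176). Gata3, a factor required for T cells, was at least 50.1-fold lower and Cd28 at least 32.0-fold lower, whereas Lat, an adaptor, rose by 2.90 (SE 0.29). Of 12 progenitor genes, 9 fell and 1 rose (camera adjusted p = 0.00646), with Hoxa9 down by 5.08 (SE 0.12), Notch1 down by 2.49 (SE 0.10) and Erg up by 4.50 (SE 0.17). Cell-cycle genes rose for 19 of 24 members (median 0.97, camera adjusted p = 3.8e-06), including Ccnd3, the cyclin D used by pro-B cells (2.64, SE 0.10), and Rrm2, a subunit of the enzyme that makes deoxynucleotides (1.96, SE 0.13). For these 4 lists the adjusted p was 0.647 with an estimated correlation.

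The dendritic cell list did not pass (5 of 10 lower, 1 higher, camera adjusted p = 0.0607), though Bst2 fell by 3.19 (SE 0.08) and Cd83 by 3.11 (SE 0.43). Myeloid genes did not shift as a list (adjusted p = 0.783), with Fcgr3 (-2.97, SE 0.10), Cebpa (-3.07, SE 0.41) and Cebpb (-3.32, SE 0.49) lower. In RAG1-/- replicate 2, 8 of 13 myeloid genes and 5 of 5 mast cell genes were more than 2-fold brighter than in replicate 1, with medians of 1.64 and 2.17 for replicate 2 less replicate 1. FOXO and IL-7 receptor targets moved both ways, 5 of 17 up and 5 down (adjusted p = 0.971): Bcl2, a survival factor, fell by 3.83 (SE 0.34), Bcl2l11, its death-promoting antagonist BIM, by 2.44 (SE 0.09), and S1pr1, a receptor for exit from tissues, rose by 2.68 (SE 0.23). E and Id proteins with Notch targets had 8 of 15 higher and 4 lower (adjusted p = 0.277), with Hes5 up by 4.43 (SE 0.19). Interferon (adjusted p = 0.124), stress (0.294), erythroid (0.868), mast cell (0.774), stromal (0.868) and ribosomal protein (0.283) lists did not pass, although Fos, an immediate early gene, fell by 5.50 (SE 0.20). Median and mean differed in sign for the myeloid, erythroid and FOXO lists.

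Leaving out EBF-/- replicate 1 lowered the calls to 1020 higher and 1241 lower, and leaving out EBF-/- replicate 2 lowered them to 1110 and 1346. Without RAG1-/- replicate 1 B-lineage factors (adjusted p = 0.104) and B cell surface genes (adjusted p = 0.0709) missed the threshold, and interferon genes passed as lower (adjusted p = 0.00451), as they did without EBF-/- replicate 2 (adjusted p = 0.00589). V(D)J recombination passed without EBF-/- replicate 1 (adjusted p = 0.0339) and without RAG1-/- replicate 2 (adjusted p = 0.0281). Dendritic cell genes passed as lower without E2A-/- replicate 1 (adjusted p = 0.0313), E2A-/- replicate 2 (0.0332), EBF-/- replicate 1 (0.0478), EBF-/- replicate 2 (0.0126) or RAG1-/- replicate 1 (0.0316). Without E2A-/- replicate 1, RAG1-/- replicate 2 and the dye term the counts were 2509 and 2899, V(D)J recombination (adjusted p = 0.026) and dendritic cell genes (adjusted p = 0.0331) then passed as lists, and the 7 lists above passed as before.

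RAG1-/- against E2A-/- compared committed pro-B cells with cells that lack E2A. Of 16 B-lineage transcription factors 13 rose, with Ebf1 up by 6.32 (SE 0.48, 79.7-fold, limma adjusted p = 0.0013), Foxo1 by 6.15 (SE 0.45, adjusted p = 0.00121), Pax5 by 6.02 (SE 0.70, adjusted p = 0.00374) and Irf4 by 6.00 (SE 0.70). Of 12 interferon-response genes 10 fell, with Irf7, the factor that amplifies the response, down by 5.66 (SE 0.33, adjusted p = 0.000765). Of 12 progenitor genes 9 fell and 2 rose, and of 11 NK genes 6 fell and 1 rose, among the lower ones Flt3 (-6.49, SE 0.10, adjusted p = 0.00025) and Tyrobp (-4.46, SE 0.11, adjusted p = 0.000263). As lists these passed camera with its preset correlation. With an estimated one, under which hardly any list could pass, the camera adjusted p was 0.667 for the factors and 0.647 for the others. By fry the factors did not pass (adjusted p = 0.0928), and the other lists did. Rag1 rose by 5.84 (SE 0.27), Tcf3 by 4.76 (SE 0.43) and Ctcf by 1.01 (SE 0.09). There were 2832 genes higher and 2942 lower in RAG1-/- cells, 1465 and 1612 of them by more than 2-fold, and 241 and 165 with a bound only.

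Atp1b1, a subunit of the sodium pump, rose by 10.16 (SE 0.52, adjusted p = 0.000639), Pou2af1 by 10.00 (SE 2.34), Lef1 by 9.10 (SE 1.54), Prkcb, a protein kinase C of B cell signalling, by 8.92 (SE 1.05) and Igll1 by 8.18 (SE 1.94, adjusted p = 0.0275). Each of these 5 was well above background in 1 of the E2A-/- samples, and replicate 1 was the brighter, as for Igll1 (11.13 against 4.33) and Pou2af1 (11.35 against 3.31). Il18r1 was at least 216-fold lower (adjusted p = 0.00025). Ccl4, a chemokine of macrophages and NK cells, fell by 9.03 (SE 0.32), Hmga2, a chromatin protein of fetal and stem cells, by 6.62 (SE 0.47), and Adgre1, which encodes the macrophage marker F4/80, by 6.60 (SE 1.15). The interferon-induced genes Rsad2 (-7.05, SE 0.82) and Mx1 (-6.77, SE 0.61) were also among the largest falls, and these 2, Ccl4 and Adgre1 were well above background in 1 of the RAG1-/- samples.

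Of 16 B-lineage factors, 13 rose and 2 fell (camera adjusted p = 0.00569), of 14 pre-B receptor genes 9 rose and 1 fell, or 11 and 2 when adjusted over the list alone (camera adjusted p = 0.0151), and of 12 surface genes 8 rose and 2 fell (camera adjusted p = 0.0355). Bank1 fell by 4.12 (SE 0.30) and Cd81 by 0.80 (SE 0.08), against their lists. With an estimated correlation these had adjusted p = 0.667, 0.667 and 0.708. By fry they did not pass either (adjusted p = 0.0928, 0.1 and 0.1). V(D)J recombination genes rose for 8 of 11 members and fell for 2 (camera adjusted p = 0.0199), with Dntt up by 7.13 (SE 0.30), Xrcc5 by 5.43 (SE 0.16) and Lig4 by 4.54 (SE 0.15). Interferon genes fell for 10 of 12 members, and for 12 of 12 when adjusted over the list alone (median -5.28, camera adjusted p = 3.26e-05). Their level differed between the RAG1-/- samples, 8 of 12 being more than 2-fold dimmer in replicate 2 (median of replicate 2 less replicate 1, -1.42). Progenitor genes fell for 9 of 12 members and rose for 2 (camera adjusted p = 0.0199), NK genes fell for 6 of 11 and rose for 1 (adjusted p = 0.0123), dendritic cell genes fell for 5 of 10 (adjusted p = 0.0256), and cell-cycle genes rose for 18 of 24 and fell for 1 (adjusted p = 2.21e-05). Siglech, a receptor of plasmacytoid dendritic cells, fell by 6.37 (SE 0.78), and Tyms, thymidylate synthase, rose by 1.35 (SE 0.08). The adjusted p of these 6 lists was 0.647 with an estimated correlation.

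Stress genes fell for 10 of 15 members and rose for 3 (camera adjusted p = 0.0406, adjusted p = 0.647 with an estimated correlation), with Fos down by 6.52 (SE 0.21) and Gadd45b up by 1.73 (SE 0.15), and this call ended in the fit without E2A-/- replicate 1, RAG1-/- replicate 2 and the dye term (adjusted p = 0.053). Myeloid genes did not pass with all samples (adjusted p = 0.0607) and passed as lower without E2A-/- replicate 1 (0.0157), EBF-/- replicate 1 (0.0202), EBF-/- replicate 2 (0.017) or RAG1-/- replicate 2 (0.00613), and in the fit without both samples (0.00219). E and Id proteins with Notch targets (0.12) passed as higher without E2A-/- replicate 1 (0.0338) and in the fit without both samples (0.048). Fcgr3 fell by 3.86 (SE 0.10) and Cebpa by 4.24 (SE 0.41), and Nrarp, a Notch target, was at least 6.41-fold higher. T-lineage genes went both ways, 4 of 11 up and 3 down (adjusted p = 0.911), with Lck up by 2.41 (SE 0.11), Gata3 at least 14.0-fold lower, and a median and mean of opposite sign. FOXO targets (adjusted p = 0.868), erythroid (0.847), mast cell (0.865), stromal (0.971) and ribosomal protein (0.847) lists did not pass, and the stromal list had a positive median and mean with a negative test direction.

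Leaving out either E2A-/- replicate 1 or E2A-/- replicate 2 lowered the number of genes called in both directions. Without RAG1-/- replicate 1 the pre-B receptor (adjusted p = 0.084) and B cell surface lists (adjusted p = 0.113) missed the threshold. The fit without E2A-/- replicate 1, RAG1-/- replicate 2 and the dye term called 2670 and 2810 genes.

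E2A binding was compared between EBF-/- pre-pro-B and RAG1-/- pro-B cells to see where E2A sits before and after commitment. The RAG1-/- list held 11846 E2A peaks and the EBF-/- list 4531. Of the RAG1-/- peaks, 17.1% (95% interval 16.4 to 17.8) overlapped an EBF-/- peak, and of the EBF-/- peaks 44.7% (43.3 to 46.2) overlapped a RAG1-/- peak, against 0.0756% and 0.197% for shifted positions. With both lists at the length of the shorter by score, 27.9% were shared in either direction. The highest-scoring E2A peak of EBF-/- cells (mm8, 10:39947916-39948115) and the peak ranked 2 in RAG1-/- cells (10:39947943-39948142) lay 4.1 kb from the Gtf3c6 probe. In RAG1-/- cells an E2A peak with a score of 83 lay 3.0 kb from the Igll1 probe (16:16777595-16777794), and a peak with a score of 66 lay 26.7 kb from Pou2af1 (9:50965339-50965538). Within 50 kb of the Rag1 probe there were 7 E2A peaks in RAG1-/- cells and 0 in EBF-/- cells, around Cd79b 5 and 0, and around Notch1 0 and 1. Whether these sites are exonic, intronic or intergenic is not given in the sources used here.

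EBF1 and FOXO1 were set against E2A in RAG1-/- cells to see how often the 3 factors meet. The EBF1 list held 1402 peaks, of which 48.6% (46.0 to 51.2) overlapped an E2A peak. The FOXO1 list held 1575, of which 42.0% (39.6 to 44.4) did, while 5.02% (4.04 to 6.21) overlapped an EBF1 peak. Shifted positions gave 0.21%, 0.145% and 0.014%. Of 38838 CTCF peaks, 3.63% (3.45 to 3.82) overlapped E2A, against 0.194% for shifted positions. These shares depend on list length, and the CTCF list is by far the longest. Over shifted positions they were 231-fold for EBF1, 290-fold for FOXO1 and 18.7-fold for CTCF. Seen from the E2A list, 5.75% of peaks met EBF1 and 5.58% met FOXO1. CTCF met 8.39% of the E2A peaks also listed in EBF-/- cells and 12.6% of those listed only in RAG1-/- cells. At equal list lengths 13.8% of EBF1 and 16.1% of FOXO1 peaks met an E2A peak, and CTCF was not compared that way. Within 50 kb of Igll1 lay 4 E2A, 2 EBF1 and 1 FOXO1 peaks, with all 3 factors at 1 place (E2A 16:16809612-16809811, EBF1 16:16809634-16809833, FOXO1 16:16809766-16809841). At Cd79a an EBF1 peak (7:24605988-24606187) coincided with E2A, 1.9 kb from the probe.

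The mock immunoprecipitation list (807 peaks) met 4.99% (3.97 to 6.26) of EBF1 peaks, the highest share of any list, and 0 of 1575 FOXO1 peaks (upper limit 0.243%). It met 1.94% of E2A peaks in EBF-/- and 0.591% in RAG1-/- cells. The highest-scoring EBF1 peak and the EBF-/- E2A peak ranked 2, both 61.1 kb from the Axin2 probe, overlapped a mock peak.

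**Figure D2:**
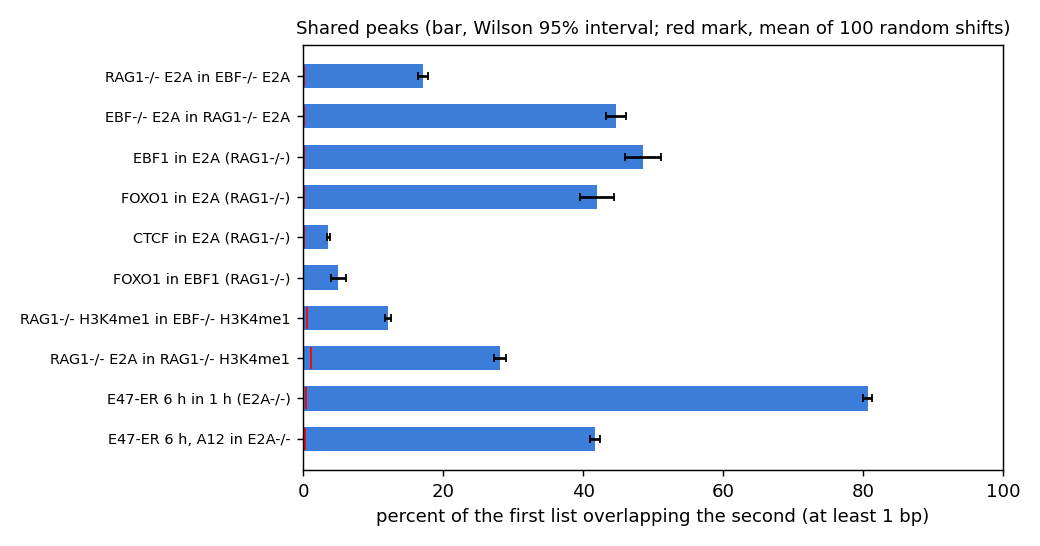
Percent of peaks in the first-named list that overlap the second-named list by at least 1 bp (bars from 0), for 10 pairs of lists, with Wilson 95% intervals for counting error and a red mark for the mean of 100 random shifts. The 6 h E47-ER peaks met 1 h peaks most often (80.7%), EBF1 and FOXO1 peaks met E2A at 48.6% and 42.0%, and the highest mean of shifted positions was 1.13%.

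Histone marks were compared between the same cells to ask how chromatin differs across commitment. H3K4me1, a mark of enhancers, was listed at 23054 places in RAG1-/- and 7544 in EBF-/- cells, and 12.1% (11.7 to 12.6) of the first and 37.1% (36.0 to 38.2) of the second were shared. H3K4me2 lists were of like length (26549 and 27025) and shared 63.6% and 62.4%. H3K4me3, found at promoters, was shared for 66.0% of RAG1-/- and 96.2% of EBF-/- peaks, and histone H3 acetylation for 80.1% and 74.1%. The repressive mark H3K27me3 was shared for 13.4% and 21.8%. Of E2A peaks in RAG1-/- cells 28.1% (27.3 to 28.9) lay in H3K4me1 peaks of the same cells, against 1.13% for shifted positions and 5.55% (5.33 to 5.78) of CTCF peaks. E2A peaks not listed in EBF-/- cells lay in EBF-/- H3K4me2 peaks in 24.6% (23.8 to 25.5) of cases and those listed in both in 46.1% (44.0 to 48.3), whereas in RAG1-/- H3K4me2 peaks the shares were 42.2% and 44.8%. The sets stayed apart in RAG1-/- H3 acetylation (16.9% and 30.3%) and H3K4me3 (15.5% and 26.3%), and in RAG1-/- H3K4me1 the order was the other way (29.1% and 23.2%). E2A peaks that met EBF1 had EBF-/- H3K4me2 in 21.4% (18.5 to 24.7) and RAG1-/- H3K4me2 in 49.3% (45.6 to 53.1) of cases.

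Genes near the factors were then set against the array changes of RAG1-/- over EBF-/- cells. Genes higher in RAG1-/- cells were near EBF1 peaks in 16.5% of cases against 11.7% of genes not called (odds ratio 1.49, 95% interval 1.31 to 1.69, Fisher's exact test, adjusted p = 1e-08). They were also more often near E2A (odds ratio 1.37, 1.25 to 1.5, adjusted p = 2.23e-10) and FOXO1 peaks (1.29, 1.14 to 1.46, adjusted p = 0.000131), but not near CTCF peaks (1.06, 0.897 to 1.24, adjusted p = 0.577). A CTCF peak lay near 91.7% of the higher genes and 91.3% of those not called, so CTCF is a weak comparator at this distance. Genes lower in RAG1-/- cells were more often near E2A (1.23, 1.13 to 1.34, adjusted p = 1.58e-05) and CTCF peaks (1.48, 1.25 to 1.76, adjusted p = 2.21e-05). E2A peaks of EBF-/- cells were more often near the lower genes (1.44, 1.32 to 1.57, adjusted p = 1.35e-14) and less often near the higher ones (0.848, 0.771 to 0.932, adjusted p = 0.00143). Of genes near 0, 1, 2 or 3 of the factors E2A, EBF1 and FOXO1, 18.5%, 20.2%, 24.1% and 31.0% were higher in RAG1-/- cells, and between 21.7% and 24.8% were lower. The 144 higher genes near all 3 included Igll1, Vpreb1, Vpreb2 and Cd79a of the pre-B receptor, the kinase Blk and the surface receptor Cd22. Genes are not independent replicates, and a peak list can place several genes near 1 peak.

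**Figure D3:**
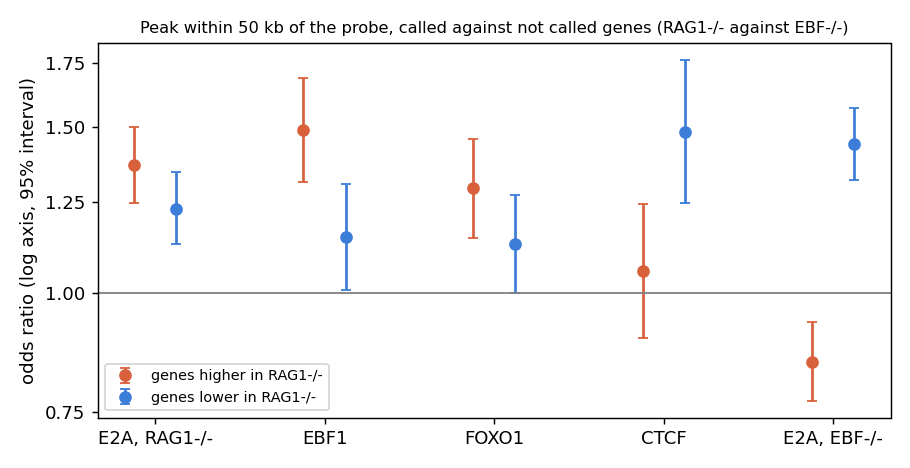
Odds ratios on a log axis, with 95% intervals, for genes higher or lower in RAG1-/- than in EBF-/- cells to lie within 50 kb of a peak, against genes not called, for 5 peak lists. Higher genes lie above 1 for E2A (1.37), EBF1 (1.49) and FOXO1 (1.29) and near 1 for CTCF (1.06), and E2A peaks of EBF-/- cells lie above 1 for lower genes (1.44) and below 1 for higher genes (0.848).

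For EBF-/- over E2A-/- cells, higher genes were more often near EBF1 (odds ratio 1.28, adjusted p = 0.00239), E2A (1.24, adjusted p = 0.000361) and FOXO1 peaks (1.20, adjusted p = 0.0216) of RAG1-/- cells. Lower genes did not pass for EBF1 (0.925, adjusted p = 0.47) or E2A (1.13, adjusted p = 0.0653). At 20 kb none of the 3 tests of higher genes passed (adjusted p = 0.0849 for EBF1, 0.057 for E2A and 0.36 for FOXO1, Fisher's exact test). For E2A peaks of the EBF-/- cells themselves, higher genes passed (1.15, adjusted p = 0.01975), though not at 20 kb (adjusted p = 0.0856), and lower genes did not (0.91, adjusted p = 0.163). For RAG1-/- over E2A-/- cells, higher genes were more often near EBF1 (1.53, adjusted p = 2.23e-10), E2A (1.29, adjusted p = 1.03e-07) and FOXO1 peaks (1.24, adjusted p = 0.0012), the last not at 20 kb (adjusted p = 0.0657). Lower genes were also more often near E2A (1.19, adjusted p = 0.000353) and CTCF peaks (1.45, adjusted p = 5.54e-05). At 20 kb 7 tests of E2A, EBF1 and FOXO1 passed, and at 50 kb 11 of 18.

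E47-ER in E2A-/- cells was followed at 1 and 6 h of tamoxifen to see where returning E2A binds. The lists held 26792 and 15386 E2A peaks. Of the 6 h peaks 80.7% (80 to 81.3) were listed at 1 h, and of the 1 h peaks 46.3% (45.7 to 46.9) at 6 h. E2A peaks of EBF-/- cells met the 6 h list in 48.8% (47.4 to 50.3) of cases and E2A peaks of RAG1-/- cells in 26.3% (25.6 to 27.1). In the other direction the order was reversed: 14.4% of the 6 h peaks met the EBF-/- list and 20.3% the RAG1-/- list. The EBF-/- list is the shorter (4531 against 11846 peaks), so the values do not show which pattern E47-ER follows. Within 50 kb of the probe, 12 peaks were listed at 1 h and 7 at 6 h for Notch1, and 0 and 0 for Pax5 and Ebf1. The window covers only part of a long gene, as the second Ebf1 probe (11:44492539-44492598) lies outside it. A count of 0 is therefore no sign that the gene is unbound. The highest-scoring 1 h peak (10:79813478-79813677) lay 0.4 kb from the probe of Tcf3, where reads of the introduced E47 sequence would also map, so it is not taken as a binding site, and the highest 6 h peak (11:3057769-3057968) lay 25.1 kb from Sfi1.

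H3K4me1 after E47-ER was compared with bHLH-ER, which lacks the transactivation domains. Of 11169 H3K4me1 peaks with E47-ER at 6 h in E2A-/- cells, 48.6% (47.7 to 49.6) were not in the bHLH-ER list, and of 17146 bHLH-ER peaks 66.5% (65.8 to 67.2) were not in the E47-ER list. In A12 cells the shares were 47.8% (46.8 to 48.8) of 10185 and 54.3% (53.4 to 55.2) of 11624. Without replicate libraries these shares cannot be set against the spread of repeated lists. E2A binding in A12 cells (17030 peaks) met that of E2A-/- pre-pro-B cells at 6 h in 41.7% (40.9 to 42.4) of cases, and 46.1% (45.4 to 46.9) in the other direction. A peak ranked 2 in A12 cells lay 54.0 kb from Notch1 (2:26335362-26335561), and A12 cells had 10 peaks within 50 kb of the Notch1 probe.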

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

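Of the tests in this part, the crossed block, the fit without E2A-/- replicate 1, RAG1-/- replicate 2 and the dye term (called without both samples below), the list tests with a sample left out and the odds ratios for EBF-/- E2A peaks were chosen only after the results were seen. Counts for RAG1-/- against EBF-/- stayed within 1.5 times of the values given in 16 of 18 alternatives in each direction, and for RAG1-/- against E2A-/- in 17 (higher) and 16 (lower), the exceptions being samples left out. For EBF-/- against E2A-/- 8 of 18 did so in each direction. With one sample left out the counts ran from 207 to 2744 higher and 217 to 2491 lower for EBF-/- against E2A-/-, from 1020 to 2673 and 1241 to 3291 for RAG1-/- against EBF-/-, and from 1586 to 2969 and 1587 to 3397 for RAG1-/- against E2A-/-. A group left with 1 sample is assumed to vary like the others, and 1 residual degree of freedom remained. Other moved counts, all for EBF-/- against E2A-/-, were 1033 and 866 without the filter on dim probes, 1048 and 926 without a trend, and 2806 and 2541 with only the 4 samples, and the cause was not tested. The replicate block gave 2665 and 2410 genes. Deviations of same-numbered samples correlated with r of -0.40 (E2A-/- and EBF-/-), 0.17 (E2A-/- and RAG1-/-) and 0.01 (EBF-/- and RAG1-/-), so the numbers share no known batch. With 2 samples per group, a negative r for same numbers equals a positive one for crossed numbers. E2A-/- replicate 2 and EBF-/- replicate 1, which are crossed, shared array 2. E2A-/- and RAG1-/- replicate 1 shared array 1, and EBF-/- and RAG1-/- samples shared none. Positive values thus fell on pairs of 1 array, although the array correlation of the fit was -0.036. With the EBF-/- numbers crossed the counts were 1183 and 958. The fit without both samples rests its spread on the EBF-/- samples.

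Of the 54 list tests, 22 passed. Camera with an estimated correlation passed 0 after adjustment and 1 at an unadjusted p under 0.05, where the preset gave 26, and fry passed 21. Fry made the same call as the preset in 39 of 54 tests. In both comparisons with RAG1-/- cells it passed none of the pre-B receptor, B-lineage factor and B cell surface lists (fry adjusted p from 0.0571 to 0.1). It passed others that the preset did not, such as V(D)J recombination in RAG1-/- against EBF-/- (fry adjusted p = 0.0148). The estimated correlation was 0.41 for the pre-B list, 0.52 for the factors and 0.66 for interferon genes. With 2 residual degrees of freedom the estimated-correlation test could hardly pass any list, so its 0 decides nothing. Normexp gave 25, 75th percentile scaling 24, no dye term 24, no array block 22, the replicate block 22, and the fit without both samples 25, with 47 of 54 calls as before. With 1 sample left out 20 to 26 passed.

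Over 283 named-gene results, 4641 of 4951 alternative values kept direction and side of the threshold, 96 gained a call, 196 lost one and 18 turned sign. One that turned was a called result, Acta2 in RAG1-/- against E2A-/- (-0.61), at 0.12 with the mean of its probes. The others were not called: Rpl3 in RAG1-/- against E2A-/- (0.027 with 75th percentile scaling), and in EBF-/- against E2A-/- Fcer1a (0.87 without E2A-/- replicate 1, 0.81 without both samples), and Itga2b (-0.66 without E2A-/- replicate 2). With 1 sample left out the range was -2.06 to 1.41 for Fcer1a, -1.34 to 0.38 for Col1a2, -0.029 to 1.75 for Gata1, -0.98 to 1.47 for Itga2b and -0.19 to 1.37 for Foxo1. In RAG1-/- against EBF-/- the range was -6.31 to 0.63 for Cpa3, -0.46 to 2.76 for Bgn and -0.39 to 3.19 for Prss34 (-0.11 without both samples). In RAG1-/- against E2A-/- it was -0.081 to 6.85 for Cpa3 and -0.15 to 3.42 for Prss34, which stood at -0.71 and -0.41 without both samples. Of 120 alternative odds ratios 106 were as before, 5 gained and 5 lost a call, and 4 uncalled ones crossed 1: 0.984 for higher genes of RAG1-/- over EBF-/- near CTCF at 20 kb, 0.974 (100 kb) and 0.999 (tertiles) for lower genes of EBF-/- over E2A-/- near FOXO1, and 0.994 for its higher genes near CTCF (tertiles). At 20 kb 7 of the 18 tests passed. The cause was not tested.

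Peak shares under 50% overlap, the upper 50% by score and equal list length, in that order, were 16.2%, 18.4% and 27.9% for RAG1-/- E2A in EBF-/- E2A, 42.2%, 48.0% and 27.9% for the reverse, 44.6%, 42.6% and 13.8% for EBF1 in E2A, and 37.5%, 37.0% and 16.1% for FOXO1 in E2A. They were 9.6%, 8.09% and 12.6% for RAG1-/- H3K4me1 in EBF-/-, 23.5%, 21.5% and 21.8% for E2A in H3K4me1, 76%, 82.4% and 66.1% for 6 h in 1 h E47-ER peaks, 54.4%, 55.7% and 58.9% for E47-ER H3K4me1 not in bHLH-ER, 51.4%, 51.1% and 51.2% for the same in A12, and 38.6%, 40.8% and 43.7% for A12 in E2A-/- E2A peaks. FOXO1 in EBF1 moved to 3.81% in the upper 50%. The cause was not tested. Removing peaks in the mock list moved none of these shares beyond its interval. Signal over background limits the arrays: the lowest well-measured log2 signal was 6.86 in E2A-/- replicate 2 and 6.26 in EBF-/- replicate 1, against 3.92 in E2A-/- replicate 1.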

Other observations

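The tests of the myeloid and B-lineage patterns below, and of genes near histone peaks or near the 2 sets of E2A peaks, were chosen only after the results were seen. So was the fit without both samples, whereas the tests of H3K4me1 with E47-ER were chosen before. Genes lower in RAG1-/- than in EBF-/- cells were more often near EBF-/- H3K4me2 (odds ratio 1.95, 1.63 to 2.32, Fisher's exact test, adjusted p = 1.02e-13), H3 acetylation (1.48, adjusted p = 6.15e-09) and H3K4me1 peaks (1.29, adjusted p = 3.07e-08), and RAG1-/- H3K4me2 (1.71, adjusted p = 8.85e-10), H3 acetylation (1.18, adjusted p = 0.0146) and H3K4me1 peaks (1.46, adjusted p = 6.81e-08). For H3K4me3 they passed in EBF-/- (1.13, adjusted p = 0.0391) and not in RAG1-/- cells (1.12, adjusted p = 0.0822). Genes higher in RAG1-/- cells were less often near EBF-/- H3K4me1 (0.823, adjusted p = 6.7e-05), H3K4me2 (0.849, adjusted p = 0.0391), H3K4me3 (0.778, adjusted p = 5.92e-06) and H3 acetylation peaks (0.804, adjusted p = 0.000598). They were not more often near RAG1-/- peaks of H3K4me1 (1.04, adjusted p = 0.758), H3K4me2 (1.15, adjusted p = 0.0942), H3K4me3 (1.01, adjusted p = 0.925) or H3 acetylation (0.996, adjusted p = 0.952) at the threshold. RAG1-/- H3K27me3 peaks were less often near the higher genes (0.806, adjusted p = 0.00267) and more often near the lower ones (1.15, adjusted p = 0.0322). E2A peaks of RAG1-/- cells that were not listed in EBF-/- cells lay near 57.9% of the higher genes (odds ratio 1.40, 1.28 to 1.54) and 52.3% of the lower (1.12, 1.03 to 1.22), and those listed in both lay near 20% of the higher (1.14, 1.01 to 1.27) and 23.9% of the lower (1.43, 1.29 to 1.59).

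The sex-linked transcripts of these mouse cultures differed between the RAG1-/- samples: Xist read 5.89 in replicate 1 and 14.40 in replicate 2, and Eif2s3y, on the Y chromosome, 12.47 and 3.38. Both Xist (14.03 and 13.78) and Eif2s3y (11.74 and 11.38) were bright in the EBF-/- samples, and in E2A-/- samples Xist read 14.67 and 14.66 and Eif2s3y 3.06 and 4.63. On array 1, 6 genes were dim in both channels and nowhere else, and on array 2 there were 2 such genes. The 3 highest-scoring E2A peaks of A12 cells included a pair near Sfi1, at 11:3042481-3042680 and 11:3057790-3057989.

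B-lineage transcripts were brighter in E2A-/- replicate 1 than in replicate 2: over 124 probes bright in RAG1-/- replicate 1 and dim in E2A-/- replicate 2, the excess had a median of 2.36% of the RAG1-/- signal (quartiles 1.44 and 3.53), with 123 above 0. Signal from the other channel of array 1, or RNA of that RAG1-/- sample, would bring its Y-linked transcripts at a like share, and their excess was -0.0858%, although the only other shared array also gave 2.59% over 15 probes. B-lineage genes active in the E2A-/- cells themselves stay open: the excess at Tcf3 was 4.01%, but its probe was well above background in E2A-/- replicate 2 too (9.45), so this value decides nothing. Cells or RNA of a pro-B kind that has E2A also stay open, as 85.5% of the probes lay within 3 times the median share. The pre-B list's median in EBF-/- against E2A-/- was -1.41 with all samples and -0.075 in the fit without both samples. RAG1-/- replicate 2 is in neither group of that comparison, so the list's shift rests on E2A-/- replicate 1.

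Myeloid and mast cell transcripts were brighter in RAG1-/- replicate 2 than in replicate 1, by a median of 1.88 over 18 list members with 13 above 1. Mpo, myeloperoxidase, read 14.60 against 9.13, S100a9 12.80 against 5.20 and Cpa3, a mast cell protease, 10.52 against 4.94. Cells or RNA like the E2A-/- or EBF-/- cultures would bring the bright transcripts of both at a like share, but the excess at Mpo was 100.2 times their median of 0.908%, and S100a9 read 3.56 and 2.95 in the E2A-/- and 2.96 and 2.95 in the EBF-/- samples. Myeloid and mast cells in the RAG1-/- culture stay open: the members' median lay at percentile 100 of 10000 random lists matched on level, but these are the lists in which the pattern was seen, so this does not test the source. The labels name a B220 enrichment before the expansion, but its purity is not given in the sources used here. No biological explanation was tested.

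H3K4me1 peaks of E2A-/- cells that were listed with E47-ER and not with bHLH-ER met 6 h E47-ER peaks in 14.9% of cases (14.0 to 15.9, of 5433), and those listed with bHLH-ER and not with E47-ER in 6.99% (6.54 to 7.48, of 11410). Unequal list length as the whole account is argued against by lists of equal length, 14.3% against 9.42%, a difference of 4.91 percentage points with intervals apart. The difference was smaller than with full lists, so length may account for part of it. A general excess of regulatory regions was tested with CTCF peaks, whose factor between the sets was 0.878 (0.753 to 1.02) against 2.14 (1.88 to 2.43) for E47-ER peaks. These CTCF peaks were mapped in RAG1-/- cells, where 5.55% lay in H3K4me1 peaks. The values argue against an excess of CTCF sites but cannot decide on an excess of enhancers. What lies behind the difference was not tested, with 1 library per list and depth unknown. In A12 cells the shares were 14.7% and 11.5%, but at equal length 14.3% and 13.5% with overlapping intervals, so the pattern was not kept there.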
